A study of Rattus norvegicus with 2 samples.

How the data were processed

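RNA from rat sympathetic neurons was measured on 2 Affymetrix Rat Expression Set 230A arrays, 1 for neurons cultured alone and 1 for neurons taken from co-culture with myocytes. Per the labels' protocols, the neurons were detached from the dish with EDTA, total RNA was extracted with a column kit, and biotin-labelled cRNA was made by in vitro transcription, so each array has 1 colour. The groups were taken from the sample titles and source names. The description field of both samples names neurons grown alone as the source of the RNA, which conflicts with the title and source name of the co-culture sample, and the title and source name were followed.

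The deposited values are intensities on a linear scale, 1 per probe set and array, all above 0. Per the series' design text, the arrays were quantified with dChip 1.3, and per the submitters' processing notes MAS5 was used. Which of these gave the deposited intensity, its scaling target and its background step are not given in the sources used here, and no detection call was used here. The trimmed means of the 2 arrays (2% trimmed from each end) were 367.6 and 360.6, so the 2 arrays were at similar levels as deposited. Per array, the number of arrays and the signal above background limit the precision, and no count or depth applies.

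The deposited intensities were used without further normalization. Values below the pooled 20th percentile of both arrays (39.6) were set to it, log2 was taken, and the log2 ratio of neurons from co-culture over neurons alone was formed. A probe set passed the filter if its intensity was at or above its array's median (185.7 and 175.0) in at least 1 array, and a gene was called bright if it was at or above the 75th percentile (479 and 464) in at least 1 array. Control probe sets were left out. Of 15866 probe sets, 12783 had 1 gene symbol, 312 had several and 2771 had none in the platform annotation used here. Symbols were updated through gene identifiers to those of the GRCr8 RefSeq gene table, which was used for names alone. A gene's value was that of its brightest probe set with exactly 1 symbol, which gave 10411 genes, of which 6369 passed the filter. Actb was measured by probe sets with several symbols and Gapdh by control probe sets, so both are given from the control probe sets.

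There was 1 array per condition, so no test, p-value or replicate spread was computed. Differences of at least 2-fold were counted as a description. The technical spread was taken as the SD of the difference between the brightest and the next probe set of a gene divided by the square root of 2, within 4 groups of genes by mean log2 value. Each of 28 gene lists was described by the median log2 ratio of its genes above the filter, its SE over genes (2000 bootstrap resamples), and its percentile among 10000 random lists of the same size matched on mean log2 value in 20 bins. Lists with fewer than 5 measured genes got no percentile. The lists covered noradrenergic synthesis and transport, sympathetic transcription factors, the cholinergic phenotype, neuropeptides and granins, pan-neuronal genes, axon growth, growth inhibition and guidance, neuronal adhesion, presynaptic release, voltage-gated channels, transmitter receptors, neurotrophic factors and immediate early genes. They also covered markers of cardiac myocytes, fibroblasts and smooth muscle, Schwann and satellite glia, endothelium, macrophages and leukocytes, and the cell cycle, basement membrane and matrix, cholesterol synthesis, heat shock and unfolded protein response, glycolysis and hypoxia, interferon response and antigen presentation, apoptosis, the respiratory chain, housekeeping genes and ribosomal proteins. Another list fixed beforehand is not reported here. Several genes are on more than 1 list, as Snap25 is on the pan-neuronal and the presynaptic list.

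Named genes were chosen by a rule with 4 parts. The first took Nppa, Th, Dbh, Npy, Gap43, Tubb3, Cdh2, Actb and Gapdh whatever their values. The second took the 15 highest and 15 lowest log2 ratios among bright genes, leaving out provisional locus symbols. The third took up to 4 members of each list with the largest difference past 2-fold, or, for a list with none, up to 2 of its brightest members. The fourth took up to 6 of the brightest members of the lists of cardiac, fibroblast, glial, endothelial, macrophage and cell cycle genes. Other genes are said to be named after their values were seen, and the members of a list that ran against the rest were named that way too. The groups, the comparisons, the gene lists, this rule and the alternatives were fixed before the data were examined, except for the scaling to the spiked controls and the tests of explanations and gene sets of the closing observations, which were added after seeing the data.

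The alternatives were quantile normalization, median scaling, a lowess correction (span 0.3), scaling to the 2% trimmed mean, a floor at the 40th percentile, no floor, a pseudocount of the floor's size, filters at the 25th or 75th percentile, at the median in both arrays or none, thresholds of 1.5-fold and 3-fold, genes in place of probe sets, the mean over a gene's probe sets, leaving out probe sets for several transcripts, and random lists not matched on signal. The steps were tested on simulated data in which a co-culture array was drawn from the neurons-alone values with the technical spread and known changes. The 2-fold call found 0 of 50 probe sets changed 1.5-fold, 22 of 50 changed 2-fold, 49 of 50 changed 3-fold and 50 of 50 changed 4-fold, and it called 16 of 8116 unchanged ones. Lists of 25 genes fell outside the central 95% of random lists in 5 of 100 draws without a change, 91 of 100 with a log2 shift of -0.2 and 100 of 100 with -0.4. The technical spread does not include the spread between cultures, so these rates do not hold for a difference between the conditions. The work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9.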

Results

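Gene expression was measured in rat sympathetic neurons, the noradrenergic neurons that innervate the heart and other organs, with 1 oligonucleotide array for each of 2 culture conditions. The first array held RNA from neurons cultured alone. Per its title and source name, the other held RNA from neurons that had been grown on myocytes, a muscle target of these neurons. These were then removed from the dish with an EDTA wash. The description field of that sample names neurons grown alone, and this conflict could not be settled here. The question, per the series' design text, was which genes accompany the arrest of growth that sympathetic neurons show when they meet their target cells. Each array carried 15923 probe sets, of which 57 were controls. The median deposited intensity of the other 15866 probe sets was 185.7 in neurons alone and 175.0 in neurons from co-culture. With 1 array per condition no difference below has a replicate check, none was tested, and every value compares these 2 arrays, not the conditions.

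The gene with the largest difference among bright genes was Mgp, a secreted inhibitor of calcification made by smooth muscle and fibroblast-like cells. Its signal was 412 in neurons alone and 1603 in neurons from co-culture, 3.89-fold higher. The next highest were Cxcl1, a chemokine, at 2.48-fold (342 against 847), and Il33, an interleukin of the nucleus, at 2.39-fold (346 against 825). Crabp2, a retinoic acid binding protein, was 2.34-fold higher, the collagen gene Col5a3 2.32-fold higher, and Lcn2, an iron-binding protein of the acute phase, 2.25-fold higher (274 against 616). The beta-globin gene Hbb was 2.16-fold and the matrix proteoglycan gene Dcn (decorin) 2.13-fold higher. The rest of the 15 highest were the glial calcium-binding protein S100b (1.99-fold), Flrt2 (1.95-fold), the EGF receptor inhibitor Errfi1 (1.94-fold), Cebpb, a transcription factor of the inflammatory response (1.88-fold), the methyl-CpG binding protein Mbd2 (1.87-fold), the matrix gene Emilin1 (1.81-fold) and Plat, tissue plasminogen activator (1.80-fold).

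At the other end, Pa2g4, a growth-related RNA and chromatin binding protein, had a signal of 1900 in neurons alone and 647 in neurons from co-culture, 2.94-fold lower. Dlk1, a membrane protein of the Notch ligand family, was 2.79-fold lower (639 against 229). Eef1a2, the translation elongation factor of neurons and muscle, was 2.61-fold lower (2080 against 798). Slc6a2, the transporter that takes noradrenaline back into the terminal, was 2.54-fold lower (552 against 217), and F3, the coagulation initiator tissue factor, was 2.40-fold lower. Other genes with roles in neurons were Nsg2, a protein of neuronal endosomes (2.26-fold lower), Pnoc, the nociceptin precursor (2.14-fold lower), Cacnb3, a calcium channel beta subunit (2.12-fold lower), and the chemokine receptor Cxcr4 (2.06-fold lower). The 15 lowest also held Raver1 (2.61-fold), the proteasome subunit Adrm1 (2.28-fold), Phf13 (2.25-fold), Samd4b (2.14-fold), Spryd3 (2.05-fold) and Tbc1d9b (1.96-fold). All 3 probe sets of Cxcr4 were lower, with log2 ratios from -1.51 to -1.05, whereas the other probe set of Samd4b was higher (0.18).

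**Figure D1:**
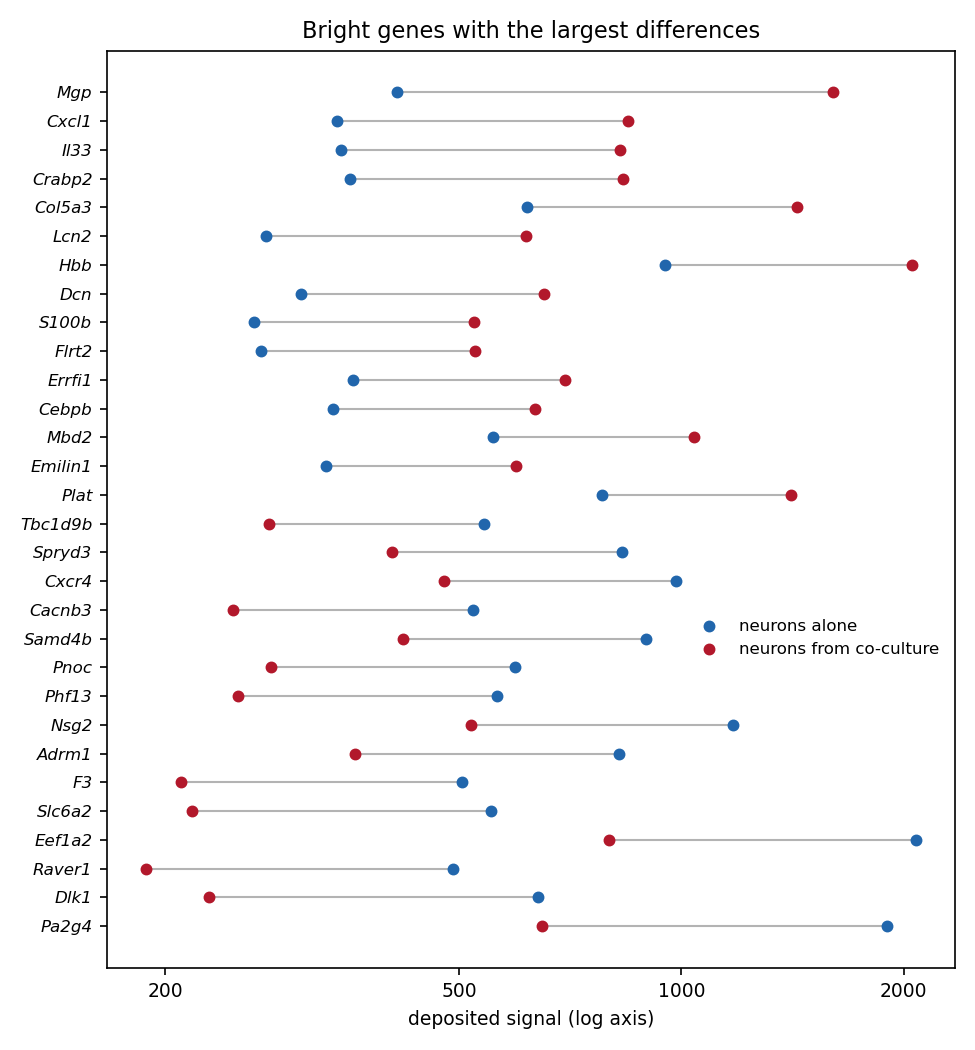
Deposited intensity (log axis) of the 15 genes with the highest and the 15 genes with the lowest ratio among genes whose brighter array was at or above the 75th percentile, with 1 array per condition. Blue points are neurons alone and red points are neurons from co-culture, as for Mgp at 412 and 1603 and Pa2g4 at 1900 and 647.

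Most transcripts were close in the 2 arrays. Of the 8308 probe sets above the signal filter, 93.8% lay within 1.5-fold, and the median log2 ratio of co-culture over alone was -0.02 (SD 0.31 over probe sets). Across probe sets, which are not independent replicates, the log2 values correlated with a Pearson r of 0.968. A difference of at least 2-fold was seen for 28 probe sets that were higher and 68 that were lower in neurons from co-culture. The higher ones made up 29.2% of these, against 40.4% after quantile normalization (36 higher, 53 lower), 39.5% after median scaling (34 and 52) and 39.8% after a lowess correction (35 and 53). Scaling to the spiked controls, chosen after seeing the data, gave 23 higher and 90 lower (20.4%). Single probe sets were noisy: 30 genes had a probe set at 2-fold and another above the filter, and the other probe sets had the same sign in 23 of them and were all at 2-fold in 1, Cxcr4. The median of the other probe sets in these genes was 0.19 on the log2 scale, taken in the direction of the largest. Among list members under 2-fold on their brightest probe set, which gives a gene's value here, another probe set was past 2-fold for Cdkn1a and, among genes not chosen by rule, for Hand2 (-1.39), Efnb1 (-1.37), Mcam (-1.36), Gabbr1 (-1.69) and Dusp6 (1.01), which were named after their values were seen. Over the 749 genes with several probe sets above the filter, the SD of 1 probe set's log2 ratio was 0.28, from 0.39 among the dimmest of 4 equal groups by signal to 0.20 among the brightest.

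**Figure D2:**
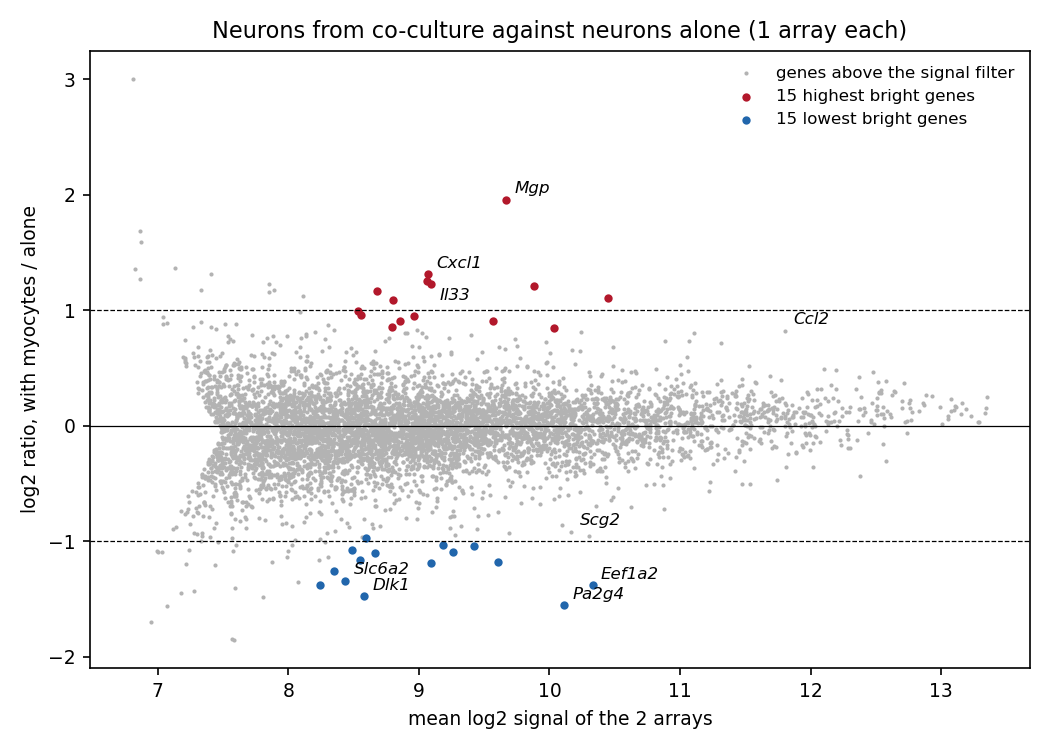
Log2 ratio of neurons from co-culture over neurons alone against the mean log2 signal of the 2 arrays, 1 point per gene above the signal filter, with dashed lines at 2-fold. The 15 highest (red) and 15 lowest (blue) bright genes lie outside a grey cloud that widens towards low signal, and 20 genes were at least 2-fold higher and 40 at least 2-fold lower.

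Genes of noradrenergic transmission were lower in neurons from co-culture. Of 9 measured genes of noradrenaline synthesis and transport, 8 were lower, the exception being Maoa, which degrades monoamines (log2 ratio 0.26, named after its value was seen). Th, the rate-limiting enzyme of catecholamine synthesis, had a signal of 6175 in neurons alone and 4575 in neurons from co-culture (1.35-fold lower), and Dbh, which makes noradrenaline from dopamine, 2159 and 1596 (1.35-fold lower). Slc6a2 was the member beyond 2-fold, and among members named after their values were seen, Gch1, which makes the cofactor of Th, was 1.76-fold lower and the vesicular transporter Slc18a2 1.24-fold lower. The list's median log2 ratio was -0.43 (SE 0.11 over genes), at percentile 0 of 10000 random gene lists matched on signal. Percentiles of lists describe these 2 arrays, since genes are not replicates. The 6 measured transcription factors of the sympathetic lineage had a median of -0.20 (SE 0.17, percentile 6.29), or -0.49 with the mean over a gene's probe sets, with none at 2-fold on its brightest probe set. Phox2a, a regulator of Th and Dbh, was 1.49-fold lower (1470 against 984), while Sox4 was at 0.12 on its brightest probe set and at -0.92 on another, and Hand2 at -0.18 and -1.39 (331 against 126, 2.63-fold lower). For the 5 measured genes of the cholinergic phenotype and gp130 receptors, the programme that some targets induce, the median was -0.07 (SE 0.20, percentile 31.9) with none at 2-fold, and under median scaling it turned to 0.01. Among them the choline transporter Slc5a7 had signals of 1101 and 1047 and the cytokine receptor Il6st 1004 and 1137. Of the 6 members below the filter, 4 had a higher and 2 a lower signal in neurons from co-culture. Among the higher ones were the acetylcholine synthesis gene Chat (21.97 and 42.26) and the vesicular transporter gene Slc18a3 (25.39 and 116). Both were named after their values were seen and were under the floor in neurons alone. With no filter the median of the list was 0.02, so these arrays do not decide whether the cholinergic programme changed.

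Genes of neuropeptides and secretory granules were lower as well. Of 19 measured members 15 were lower, with a median of -0.30 (SE 0.10, percentile 0.02), or -0.15 with no filter, and Pnoc was the 1 member past 2-fold. Npy, the peptide that sympathetic neurons release with noradrenaline, had a signal of 6799 in neurons alone and 5507 in neurons from co-culture (1.23-fold lower). Among members named after their values were seen, the enkephalin precursor Penk was 1.90-fold lower, the granin Scg2 1.89-fold lower, Gal (galanin) 1.58-fold lower and Chgb 1.46-fold lower. The 4 higher members, also picked after seeing the values, were Sst (0.60), Nmu (0.42), Edn1 (0.13) and Cck (0.11).

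Genes of vesicle release, and the channel and receptor genes above the filter, were also lower. Of 26 measured genes of synaptic vesicles and presynaptic release, 25 were lower and 1, Synj1 (0.05, or -0.05 under scaling to the spiked controls), was not. The median was -0.38 (SE 0.07, percentile 0), with Rab3a, a vesicle GTPase (3.61-fold lower, 361 against 100), and Syt9, a calcium sensor of vesicle fusion (2.12-fold lower), past 2-fold. Genes of this list picked after seeing the values were Vamp2 (1.68-fold lower), Syn2 (1.63-fold), Snap25 (1.53-fold), Syn1 (1.35-fold) and Syp (1.19-fold). Of 47 voltage-gated channel genes on the array, 38 were below the filter, and the 9 measured ones were all lower (median -0.44, SE 0.15, percentile 0.05). The median of the list was -0.25 with the filter at the 25th percentile and -0.09 with no filter. Of the 9, Cacna2d1 was at -0.04 and turned to 0.04 under quantile normalization, median scaling and lowess. Cacnb3 was past 2-fold, and Hcn2, a pacemaker channel named after its value was seen, was 1.75-fold lower. Of 15 measured receptors of neurotransmitters and neuromodulators, 13 were lower (median -0.40, SE 0.06, percentile 0.01, or -0.08 with no filter, which adds 51 dim genes), and the 2 others were P2rx4 (0.10) and Grin1 (0.00, or -0.09 under scaling to the spiked controls). Tacr1, a substance P receptor, was 2.13-fold lower, but its signal was low (186 against 87.5), and its log2 ratio of -1.09 became -0.64 with the floor at the 40th percentile. Subunits of the ganglionic nicotinic receptor, named after their values were seen, were lower by 1.75-fold (Chrnb4) and 1.32-fold (Chrna3).

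Pan-neuronal genes were lower too. The 25 measured genes of the neuronal cytoskeleton and other pan-neuronal markers had a median of -0.22 (SE 0.07, percentile 0), or -0.14 under median scaling, 22 of them were lower and none reached 2-fold. The 3 higher ones were Stmn4 (0.39), Mapt (0.16 on its brightest probe set, -0.34 without probe sets for several transcripts) and Map2 (0.12). Tubb3, the neuronal beta-tubulin, had a signal of 3641 in neurons alone and 3202 in neurons from co-culture (1.14-fold lower), a log2 ratio of -0.19 that became -0.73 without probe sets for several transcripts, on a probe set below the filter in both arrays. Prph (5008 against 4598) and Rtn1 (4380 against 3936) were 1.09-fold and 1.11-fold lower, and the neurofilament genes Nefm and Ina, picked after seeing the values, were 1.42-fold and 1.63-fold lower. The 23 measured adhesion molecules of neurons had a median of -0.25 (SE 0.09, percentile 0), or -0.16 under median scaling, with Negr1 past 2-fold at low signal (187 against 87.7; its log2 ratio of -1.09 became -0.65 with the floor at the 40th percentile). The N-cadherin gene Cdh2, an adhesion molecule of neurons and heart muscle, had signals of 1349 and 1315, a log2 ratio of -0.04 that turned to 0.05 under median scaling and was 0.10 on its other probe set.

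Genes linked to axon growth were not lower as a list, unlike the pan-neuronal genes. The 31 measured genes of axon growth and regeneration had a median of 0.09 (SE 0.08, percentile 88.3) and a mean of -0.01, so that median and mean differed in sign, and none reached 2-fold. Without the genes shared by both lists, the median of 27 growth genes exceeded that of the pan-neuronal genes by 0.33 (SE 0.09 over genes, compared after the values were seen). The shared genes left out included Stmn2 and Dpysl3, which were lower. The growth list is not restricted to neurons, as it shares Stmn1 with the cell cycle list and Gadd45a with the apoptosis list. The difference can therefore not be assigned to neurons. The median of the 31 was 0 after quantile normalization, 0.18 under median scaling and -0.00 under scaling to the spiked controls. Gap43, a protein of growing axons, had signals of 5492 and 5028 (1.09-fold lower), and Tubb2b, a tubulin of growing neurons, 5571 and 5697, a log2 ratio of 0.03 that was negative under quantile normalization (-0.10), lowess (-0.08) and scaling to the spiked controls (-0.06). Members picked after seeing the values went both ways: Atf3, a transcription factor induced by axon injury, was 1.72-fold higher and Gadd45a 1.56-fold higher, while Dpysl3 was 1.83-fold lower and Stmn2 1.28-fold lower. The 21 measured ligands and receptors of growth inhibition and guidance had a median of -0.12 (SE 0.08, percentile 7.86), or -0.03 under median scaling, and the 1 member at 2-fold was Sema6b, a transmembrane semaphorin (2.01-fold lower, 250 against 125). The 22 measured neurotrophic factors and their receptors had a median of -0.13 (SE 0.09, percentile 4.80), or -0.05 under median scaling and -0.23 under scaling to the spiked controls, with none at 2-fold. The neurotrophin receptor gene Ngfr had signals of 2453 and 2275, and the activin antagonist Fst had 1378 and 1307, a log2 ratio of -0.08 that was 0.21 on another probe set.

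**Figure D3:**
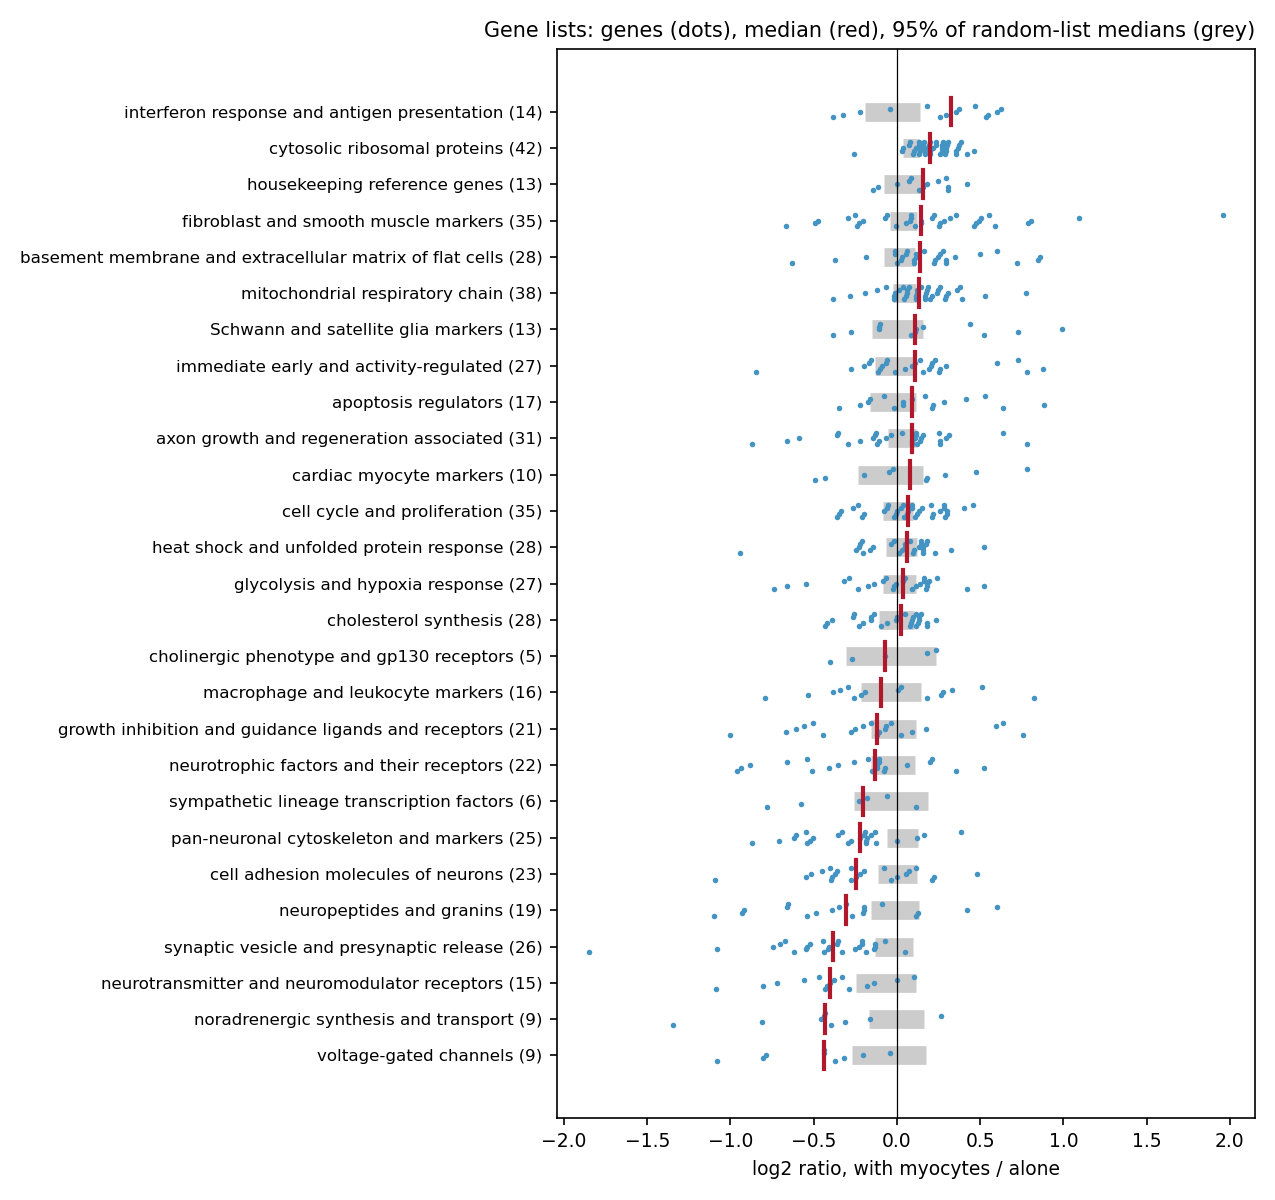
Log2 ratios of co-culture over alone for the 27 gene lists with at least 5 measured genes (number in brackets), with each gene as a dot, the list median as a red bar and the central 95% of medians of 10000 matched random lists in grey. Medians lay below the grey range for 7 lists, all of neuronal genes, and above it for 6 lists. Lists of randomly drawn genes would give 1.35 outside in all. Genes of a list can vary together and lists share genes, so this number is no test of the difference.

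Most transcripts of the heart muscle list were low in both arrays. Nppa, the atrial natriuretic peptide gene that the study used as its myocyte marker, had a signal of 178 in neurons alone and 201 in neurons from co-culture. The log2 ratio of 0.18 was smaller than the spread of 1 probe set at this signal (SD 0.39), and both values were close to the array medians. Of 38 cardiac genes on the array, 28 were below the filter in both arrays. The 10 measured ones had a median of 0.08 (SE 0.14, percentile 87.3, or -0.02 under scaling to the spiked controls), with none at 2-fold. The brightest were Ankrd1 (1643 against 1166, 1.41-fold lower) and the gap junction gene Gja1 (1404 against 1713, 1.22-fold higher), and Tnnt2, cardiac troponin T, had 293 and 408. Of the 28 genes below the filter, 15 had a higher and 13 a lower signal in neurons from co-culture, and with no filter the median of the list was 0. Named after their values were seen, the ventricular light chain Myl2 had 44.8 in neurons alone and 134 in neurons from co-culture. The myosin heavy chains Myh6 (74.3 and 134) and Myh7 (18.3 and 69.9), also named after their values were seen, were higher as well. On the lower side, named in the same way, were the calcium pump regulator Sln (63.4 and 4.94) and the creatine kinase Ckmt2 (56.0 and 19.4). The lower value of Myh7, Sln and Ckmt2 was under the floor.

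Transcripts of flat, matrix-producing cells were abundant in both arrays. In neurons alone, Col1a1 had a signal of 9988 and Vim of 8328, and 34 of the 35 measured fibroblast and smooth muscle genes were above that array's median. In neurons from co-culture Col1a1 had 10750 and Vim 8646, log2 ratios of 0.11 and 0.05 that turned negative under quantile normalization (-0.03 and -0.09) and lowess (-0.05 and -0.09). The fibroblast and smooth muscle list had a median of 0.15 (SE 0.07, percentile 99.5), or 0.23 under median scaling and 0.05 under scaling to the spiked controls, with 24 genes higher and 11 lower, and Mgp and Dcn past 2-fold. Members named after their values were seen went apart. Lum was 1.75-fold, Loxl1 1.73-fold and Postn 1.41-fold higher, whereas the contractile genes Acta2, Myl9 and Tagln were 1.39-fold, 1.18-fold and 1.17-fold lower. The contractile gene Cnn1 went the other way and was 1.20-fold higher (353 against 423). The 28 measured genes of basement membrane and extracellular matrix had a median of 0.14 (SE 0.06, percentile 99.6), or 0.23 and 0.05 under these scalings, with 23 higher and none at 2-fold, and Lamb1, named after its value was seen, was 1.65-fold higher. The collagen chaperone Serpinh1 had signals of 4759 and 5335.

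Markers of other cells gave no common direction. The 13 measured Schwann and satellite glia genes had a median of 0.11 (SE 0.13, percentile 89.4), or -0.01 with the median required in both arrays, with none at 2-fold, and Cryab (4583 against 5107) and Sox10 (706 against 750) were among the brightest. Of these genes 8 were higher and 5 lower, and the 2 past 1.5-fold, S100b (1.99-fold) and Egr2 (1.66-fold), were both higher. The 16 measured macrophage and leukocyte genes had a median of -0.09 (SE 0.15, percentile 22.8), or 0.22 with the filter at the 75th percentile, with none at 2-fold. In that list the chemokine gene Ccl2 was 1.77-fold higher (2695 against 4769) and the Fc receptor subunit Fcer1g 1.73-fold lower (796 against 460). The 3 measured endothelial genes were Eng (672 against 774), Egfl7 (211 against 191) and Icam2 (192 against 191), with none at 2-fold. The 35 measured cell cycle genes, of which 34 were above the median in neurons alone, had a median of 0.07 (SE 0.04, percentile 89.9, or -0.03 under scaling to the spiked controls) with none at 2-fold. Pcna, a replication clamp, had signals of 2998 and 3140, and Ccnd1, cyclin D1, 1858 and 2287. The cell cycle inhibitor Cdkn1a was higher on its brightest probe set (2474 against 3273) and lower on the other (967 against 483).

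Genes of the interferon response and antigen presentation above the filter were higher in neurons from co-culture. The 14 measured members had a median of 0.32 (SE 0.11, percentile 100), and 10 were higher, with none at 2-fold. The median was 0.15 with the filter at the 25th percentile and 0.08 with no filter, and of the 12 members below the filter 5 had a higher and 7 a lower signal in neurons from co-culture. B2m, the light chain of class I molecules, had a signal of 3627 in neurons alone and 4444 in neurons from co-culture (1.23-fold higher), and Ifitm3 2695 and 3492 (1.30-fold higher). The immunoproteasome genes Psmb9 and Psmb8, named after their values were seen, were 1.54-fold and 1.51-fold higher. The 4 lower members, also picked after seeing the values, were Stat2 (-0.39), Usp18 (-0.32), Oasl (-0.22) and Oas1a (-0.04, or 0.04 to 0.05 under quantile normalization, median scaling and lowess). The 27 measured immediate early and activity-regulated genes had a median of 0.11 (SE 0.08, percentile 97.6), or 0.01 under scaling to the spiked controls, with none at 2-fold. Egr1 had signals of 2382 and 2746 and the matrix gene Ccn2 6993 and 6705, and Fos and Egr2, named after their values were seen, were 1.84-fold and 1.66-fold higher while Arc was 1.80-fold lower. The 17 measured apoptosis regulators had a median of 0.09 (SE 0.09, percentile 94.4, or -0.00 under scaling to the spiked controls) with none at 2-fold, and among them Mdm2 had 1547 and 1742 and Tnfrsf12a 1549 and 1465.

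Genes of ribosomes and mitochondria were slightly higher. Of 42 measured cytosolic ribosomal protein genes, 41 were higher and 1, Rpl39 (-0.26), was lower, with a median of 0.20 (SE 0.03, percentile 100) and none at 2-fold. That median was 0.08 after quantile normalization, 0.12 after lowess and 0.11 under scaling to the spiked controls. Rpl7a had signals of 8908 and 9841 and Rps23 9929 and 10152, log2 ratios of 0.14 and 0.03 that were -0.00 and -0.12 after lowess. The 38 measured respiratory chain genes had a median of 0.13 (SE 0.03, percentile 99.3), or 0.09 after lowess and 0.04 under scaling to the spiked controls, with none at 2-fold, and Atp5mc3 had 5033 and 5558. The 13 measured housekeeping reference genes had a median of 0.16 (SE 0.06, percentile 97.2), or 0.10 and 0.06 under these settings, with none at 2-fold, and Eef1a1 had 9601 and 11389. The 3' control probe sets of beta-actin (11350 against 11867) and GAPDH (7700 against 7838) were within 1.5-fold. Lists of metabolism and stress showed medians near 0 with none of their genes at 2-fold. The 28 measured genes of cholesterol synthesis had a median of 0.02 (SE 0.07, percentile 66.8) and a mean of -0.04, the 27 of glycolysis and hypoxia a median of 0.03 (SE 0.06, percentile 60.7) and a mean of -0.02, and the 28 of heat shock and the unfolded protein response a median of 0.06 (SE 0.05, percentile 72.3). Under scaling to the spiked controls these 3 medians were -0.07, -0.06 and -0.03. Bright members of these lists were Fdps (2897 against 3170), Aldoa (6063 against 6043) and Hspd1 (5726 against 5776).

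Signs of array and RNA quality differed between the arrays, most for hexokinase. The 18 spiked bacterial and phage control probe sets were higher in the co-culture array by a median log2 ratio of 0.09 (SD 0.11). The median log2 ratio went from -0.08 in the dimmest of 4 equal groups of probe sets to 0.04 in the brightest, so genes of low signal tended to be lower and bright genes higher. The ratio of 3' to 5' signal was 1.15 in neurons alone and 1.24 in neurons from co-culture for beta-actin, 1.13 and 1.17 for GAPDH, and 2.25 and 4.17 for hexokinase, a log2 change of 0.89. The hexokinase 5' signals (180 and 76.5) were below the array medians. The ratio of 3' to middle signal was 1.07 in both arrays for beta-actin, 1.25 and 1.17 for GAPDH, and 0.62 and 1.27 for hexokinase.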

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

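Scaling to the spiked controls and all alternatives for the gene sets of the next part were chosen after seeing the data, and the other alternatives were planned. No paired analysis was possible because each condition had 1 array and the labels give no replicate numbers. A list median was taken as kept if it shifted by no more than the SD of its genes' log2 ratios divided by the square root of their number. This differs from the bootstrap SE given with the medians. List medians were kept in 307 of 372 alternatives, and the values of single named genes, within the spread of 1 probe set, in 1618 of 1645. Part of this agreement was fixed in advance, so the tallies are no measure of robustness. Median, trimmed mean and spiked-control scaling shifted genes by less than the smallest spread of 1 probe set (0.20). No named gene could therefore leave its spread under these scalings. Every list median was unchanged with the raised floor and with no floor, so these alternatives add to the tally without testing it. A filter or threshold by construction sets how many probe sets are counted. Median scaling by construction raises every list median by nearly the same amount, and scaling to the spiked controls lowers every list median alike. Which lists moved under these scalings therefore depended on the shift allowed for each list. For the other exceptions that follow the cause was not tested. Signal over background limits what can be said of genes near the floor.

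The counts of 28 higher and 68 lower probe sets at 2-fold were 17 and 43 with a pseudocount, 82 and 213 with the filter at the 25th percentile and also with no filter, 10 and 25 with the filter at the 75th percentile, and 13 and 30 with the filter at the median in both arrays. They were 159 and 352 at 1.5-fold and 5 and 9 at 3-fold, and 40 were lower when genes were counted in place of probe sets. Without probe sets for several transcripts Samd4b turned to 0.18 from -1.10.

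Among list medians, quantile normalization gave 0 for axon growth, 0.075 for cholesterol synthesis, 0.096 for the respiratory chain and 0.082 for ribosomal proteins. Lowess gave 0.0037 for axon growth, 0.066 for cholesterol synthesis, 0.0091 for heat shock, 0.086 for the respiratory chain, 0.099 for housekeeping genes and 0.12 for ribosomal proteins, which had 0.23 after trimmed mean scaling. Median scaling gave -0.14 for pan-neuronal genes, -0.16 for adhesion, -0.30 for presynaptic release, -0.32 for receptors, -0.049 for neurotrophic factors, 0.18 for axon growth, 0.19 for immediate early genes, 0.23 for fibroblast genes, 0.15 for the cell cycle and 0.23 for basement membrane and matrix. It also gave 0.11 for cholesterol synthesis, 0.15 for heat shock, 0.12 for glycolysis, 0.18 for apoptosis, 0.22 for the respiratory chain, 0.24 for housekeeping genes and 0.29 for ribosomal proteins. Scaling to the spiked controls gave -0.32 for pan-neuronal genes, -0.34 for adhesion, -0.48 for presynaptic release, -0.50 for receptors, -0.23 for neurotrophic factors, -0.0037 for axon growth, 0.013 for immediate early genes, 0.051 for fibroblast genes, -0.027 for the cell cycle and 0.045 for basement membrane and matrix. It also gave -0.069 for cholesterol synthesis, -0.031 for heat shock, -0.060 for glycolysis, 0.23 for interferon genes, -0.00090 for apoptosis, 0.039 for the respiratory chain, 0.062 for housekeeping genes and 0.11 for ribosomal proteins.

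With the filter at the 25th percentile neuropeptides had -0.20, channels -0.25 and interferon genes 0.15. With it at the 75th percentile neuropeptides had -0.47, presynaptic release -0.30, macrophage genes 0.22, cholesterol synthesis -0.028 and apoptosis 0.0066. With no filter neuropeptides had -0.15, channels -0.089, receptors -0.081, interferon genes 0.077 and apoptosis 0, and with the median required in both arrays glia had -0.0084. Without probe sets for several transcripts pan-neuronal genes had -0.31 and cholesterol synthesis -0.031. With the mean over a gene's probe sets sympathetic transcription factors had -0.49, cholesterol synthesis -0.013 and ribosomal proteins 0.22. Against random lists not matched on signal, 25 of 27 lists stayed on the same side of the central 95%, and axon growth and housekeeping genes moved above it.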

Other observations

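The tests of explanations in this part, their gene sets and the genes of the next paragraph were chosen after the results were seen, while the fixed lists and their values under other filters and lowess were planned.

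Some of the genes below the bright range that were at least 2-fold higher in neurons from co-culture encode secreted factors. Genes of this range that were at least 2-fold lower include secreted proteins too. Examples are Hamp (373 in neurons alone and 182 in neurons from co-culture), Hrg (263 and 114) and Fgfbp3 (227 and 114). Whether such factors were over-represented among the higher genes was not tested. Fibin, a secreted factor of limb development, had a signal of 23.1 in neurons alone, under the floor, and 318 in neurons from co-culture. Spon1, a matrix protein of the floor plate, had 67.6 and 203, Areg, a ligand of the EGF receptor, 87.4 and 225, and Tnfrsf11b, the decoy receptor osteoprotegerin, 158 and 357. Cd248, a marker of pericytes and fibroblasts, had 187 and 408. On the lower side were Cyp1a1, a xenobiotic-metabolising enzyme (364 and 101), Clstn3, a postsynaptic adhesion protein (223 and 68.4), and Atp2b4, a plasma membrane calcium pump (219 and 104). With the floor at the 40th percentile the log2 ratios of Spon1, Areg and Clstn3 were 0.77, 0.92 and -0.90, which is under 2-fold.

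The genes of noradrenaline synthesis, peptides, presynaptic release, channels and receptors (77 genes in all) had a median log2 ratio of -0.39, or -0.19 over 202 genes with no filter. Growth-associated genes were higher than pan-neuronal genes by 0.33 (SE 0.09 over genes), but their list is not restricted to neurons. A lower share of neurons in the RNA with all other cells raised alike would raise matrix and contractile genes of the other cells together. These differed by 0.45 (SE 0.10), but the contractile genes were set apart after their values were seen, so this did not decide it. Nor did the difference of matrix genes from the 16 leukocyte markers, 0.31 (SE 0.17). The difference from 11 of these markers, 0.43 (SE 0.13), did not decide it either, as they were picked after their values were seen. This explanation stays open. A trend with signal between the arrays was argued against, since the median after lowess was -0.34. A lower share of neurons with a changed mix of other cells stays open: the median of the 77 genes minus that of the pan-neuronal genes was -0.17 (SE 0.08), but -0.13 (SE 0.09) within 1 range of signal. Shorter labelled RNA stays open too, because the log2 ratio of 3' to 5' signal was higher in the co-culture array by 0.89 for hexokinase but by as little as 0.050 for GAPDH. The ratio of 3' to middle signal was higher there for hexokinase (0.62 and 1.27) but not for GAPDH (1.25 and 1.17) or beta-actin. An effect of contact with myocytes stays open as a hypothesis. It may act beside these explanations and cannot be separated from them with 1 array per condition. It also rests on the title and source name of the co-culture sample, with which the sample's description field conflicts.

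Matrix and fibroblast genes (57 genes without the contractile ones) had a median of 0.21. A higher share of all flat cells would raise contractile genes alike. Matrix genes exceeded the contractile genes Acta2, Tagln, Cnn1, Myh11, Myl9 and Cald1 by 0.45 (SE 0.10), although Cnn1 was itself higher (0.26). The contractile genes were set apart after their values were seen, so this difference does not decide the question and a higher share stays open. A trend with signal was argued against, as the median after lowess was 0.18. A change in the state or kind of flat cells carried over with the neurons, such as fibroblast-like cells from the myocyte dish, may account for the pattern and stays untested, as does an effect of co-culture on the flat cells already present. Under scaling to the spiked controls the median of the 57 genes was 0.12, and under median scaling 0.30.

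Genes of the interferon response and antigen presentation had a median of 0.32, and a trend with signal was argued against by a median of 0.30 after lowess. A higher share of leukocytes stays open: the 16 measured leukocyte markers had a median of -0.093, a difference of -0.42 from these genes (SE 0.20), but that median was within its SE of 0. With the filter at the 75th percentile the leukocyte list had 0.22, with Ccl2, Spp1 and Gpnmb among its higher members. The 11 markers other than chemokines, Spp1 and Gpnmb had -0.22, a difference of -0.54 (SE 0.16), but they were picked after the values were seen and 4 of the 5 left out were higher, so this decides nothing. With no filter the median of the interferon list was 0.08, and a response of neurons or flat cells to co-culture and a difference between the 2 cultures unrelated to the myocytes were not tested and stay open.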
